A study of Mus musculus with 6 samples.

How the data were processed

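RNA from LLC, AE17 and MC38 cells, 1 culture labelled sh Ctrl and 1 labelled sh Spp1 per line, was hybridised to 1-colour whole-transcript arrays. The cells grew in medium with fetal bovine serum, and the RNA was labelled with biotin. The deposited table gives linear intensities for 41345 probe sets on 6 arrays. The submitters' processing notes name RMA, and the design text names GeneSpring GX 12.5, which made the values. The values ran from 1.28 to 15526, and their medians differed between arrays, so they were taken as linear and not normalized between arrays.

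Groups came from the sample titles and cell lines from the cell line label. Each line has 1 array per group, so the line is the pair, and the 3 lines are the replicates of the comparison between shRNAs. Replicate cultures within a line were not used here, so the p-values of single genes for the shRNA measure the spread between lines.

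Intensities were log2 transformed and quantile normalized between arrays with limma 3.58.1 in R 4.3.3. The plan written before the data were examined took the deposited values as already normalized and listed quantile normalization as the alternative. The distributions of the arrays showed that this was not so, and the order was turned before any test was looked at. The values as deposited are reported as an alternative.

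Genes were named from the platform annotation. Of the probe sets, 23521 carried 1 gene symbol, 1814 several and 16010 none in the table used here. By Entrez ID 23328 matched the RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. No gene was named from a probe set with several symbols, and no probe set used here names Spp1. Probe sets with 1 symbol and a mean at or above the 30th percentile of all, a log2 intensity of 4.49, were tested. That left 17757 probe sets for 16797 genes, and the brightest probe set stood for its gene.

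The shRNA effect was fitted with lmFit and eBayes, with the cell line as a block and Benjamini-Hochberg adjustment at 0.05. Contrasts between lines came from the same additive model. The 2 arrays of a line differ in shRNA and are not replicate cultures. The error of these contrasts therefore holds line-specific responses to the shRNA together with the variation of single cultures and arrays. Within a line, where no test is possible, genes were counted by an absolute log2 ratio of at least 1 among those at or above the floor on at least 1 of the 2 arrays. Of 35 lists fixed beforehand, 26 of pathways and 9 of cell type markers, 33 had at least 5 tested members. The mast cell list, with 1, and the list of Spp1 relatives and neighbours, with 4, were not tested. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. At the preset correlation camera compares list genes with other genes. Its p-values do not measure how a list's shift varies between lines. Within a line, a list's median was placed among 10000 random lists of the same size, drawn in deciles of mean brightness. Outside the central 95% lay 33 of the 99 combinations of list and line, where lists of unrelated genes would give 4.95. Members of a fixed list can vary together, with an estimated correlation of 0.86 for interferon-stimulated genes. For such lists 4.95 is too low a measure of chance.

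The genes named follow a rule fixed beforehand. Where fewer than 12 genes passed in a direction, the rule fills to 12 with genes of the same sign in all lines, ranked by the smallest ratio and given as values. It adds the 6 highest and 6 lowest ratios per line, line genes past both contrasts, of which there were 0, and the 2 highest and 2 lowest members of each list. Clone names, predicted genes and similar symbols were passed over. Fosb, Mcm4, Mcm7 and Cdkn1a were chosen after their values were seen, as were the genes compared between MC38 and LLC.

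The fit was tested on simulated data with 200 changed probe sets in each of 10 runs. Alternatives covered the brightness filter, the scaling, the variance prior, array weights, all probe sets, the mean of a gene's probe sets, each line left out, no block, no shRNA term, and the thresholds. The tests along the chromosomes used GRCm38.p6 only for which genes neighbour each other. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.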

Results

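Transcript levels were measured on 6 arrays of RNA from cultured mouse cancer cell lines. LLC was derived from Lewis lung carcinoma, AE17 from a malignant mesothelioma and MC38 from a colon adenocarcinoma. Each line had 1 array labelled sh Ctrl and 1 labelled sh Spp1, a short hairpin RNA against Spp1. Spp1 encodes osteopontin, a secreted glycoprotein that binds integrins and Cd44. The series title sets wild-type lines against lines transfected with the hairpin, and the sh Ctrl arrays also carry the genotype label wild type, so the labels leave open whether the controls received a control hairpin. The table gave 1 intensity per array for 41345 probe sets. The level of Spp1 itself was not analysed here, because 0 of the probe sets with a gene name used here name it, so each direction below rests on the labels. The number of arrays limits the precision: every within-line value below is 1 array against 1 array, with no replicate.

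The deposited intensities had not been brought to 1 distribution. The median intensity was 64.2 on the LLC sh Ctrl array and 37.2 on the LLC sh Spp1 array, 36.3 and 26.6 in AE17, and 49.4 and 43.7 in MC38. In each line the sh Spp1 array had the wider spread, with 6.73 against 5.99 log2 units between the 10th and 90th percentiles in LLC, 6.56 against 6.0 in AE17 and 6.57 against 6.05 in MC38. After quantile normalization the arrays of a line correlated across probe sets at r = 0.979 in LLC and 0.982 in MC38, but at 0.939 in AE17. Both AE17 arrays correlated more closely with each of the 4 arrays of the other lines than with each other, the sh Spp1 array at 0.942 to 0.949 and the sh Ctrl array at 0.943 to 0.954. Probe sets are not independent replicates.

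**Figure D1:**
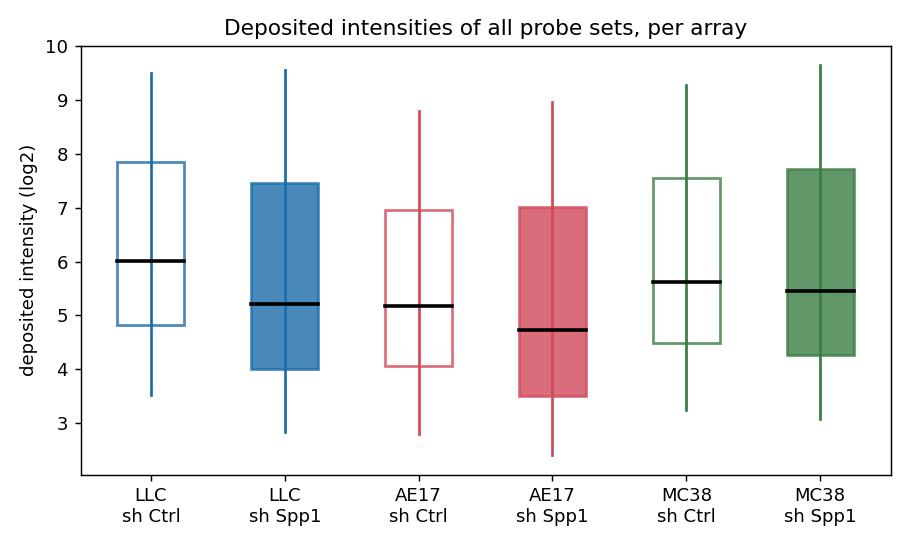
Deposited intensities (log2, vertical axis) of all probe sets on each of the 6 arrays (horizontal axis). Boxes show the interquartile range (open for sh Ctrl, filled for sh Spp1), black lines the median and vertical lines the 10th to 90th percentiles, and the sh Spp1 array had the lower median and the wider spread in each line.

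The first comparison set sh Spp1 against sh Ctrl over the 3 lines, and asked which transcripts differ with the hairpin against Spp1. Cxcl1 (Entrez gene 14825), a neutrophil chemoattractant, was lower on the sh Spp1 array of every line and had a mean log2 ratio of -1.54 ± 0.23 (SD, n = 3 lines). Ccl2 (Entrez gene 20296), a monocyte chemoattractant, had -2.15 ± 0.96, going from a log2 intensity of 11.78 to 8.59 in LLC, from 11.83 to 10.54 in AE17 and from 12.16 to 10.18 in MC38. Pdgfra, a receptor for platelet-derived growth factor, had -1.59 ± 0.39, and Dkk2, a secreted Wnt modulator, -2.10 ± 1.03. Among transcripts higher in every line, the immediate early transcription factor Egr1 had 1.73 ± 0.85 and the alpha-tubulin gene Tuba1b 1.79 ± 0.85. None of these genes passed the test.

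With limma and the cell line as a block, 0 of 16797 genes reached an adjusted p under 0.05, and the smallest adjusted p was 0.706. At an unadjusted p under 0.05 there were 1042 genes, or 6.20% of those tested, of which 591 were higher and 451 lower, and the paired test without variance moderation gave 1013. On simulated data with the spread fitted over these lines, the test recovered 98.2% of genes changed by 3 log2 units and 6.5% of those changed by 1, and 10.9% of its calls were false. With 1 spread for every gene, the median of the LLC and MC38 pairs, it recovered 99.8% of those changed by 1, and 3.76% of its calls were false. Spreads differ between real genes, so that figure does not show that AE17 alone hid such changes. Without AE17 limma still gave 0 genes, with a smallest adjusted p of 0.5905. An exact sign-flip test of 3 pairs cannot go below p = 0.25.

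The other genes with the same sign in all lines, ranked by the smallest of their 3 ratios, are given as values only. Higher on the sh Spp1 arrays were Pabpc4 at 1.16 ± 0.24 (SD, n = 3 lines), Cstf2t at 1.11 ± 0.45, Fam83h at 1.43 ± 1.01 and the ribosome biogenesis factors Rrp12 at 1.01 ± 0.15 and Pwp2 at 0.81 ± 0.10. The stress-response genes Sesn2, Zmat3, Ppp1r15a and Gadd45g had mean log2 ratios of 1.02 ± 0.21, 0.99 ± 0.16, 1.12 ± 0.39 and 1.55 ± 1.11. The immediate early gene Ier2 had 1.10 ± 0.28. Lower were Clec1a at -1.90 ± 1.05, Rbp4, the plasma carrier of retinol, at -1.36 ± 0.81, Naip6 at -1.71 ± 1.27, Sesn1 at -1.08 ± 0.38 and the transcript Platr25 at -1.37 ± 0.62. The interferon-inducible genes Herc6, Sp100 and Trim30d had -1.40 ± 0.57, -1.43 ± 0.88 and -1.57 ± 0.98. Levels under the brightness floor, a log2 intensity of 4.49, are set by background. Platr25 lay under it on all 3 sh Spp1 arrays, Naip6 on those of LLC and AE17 and Trim30d on that of LLC, so the sizes of their ratios are approximate.

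**Figure D2:**
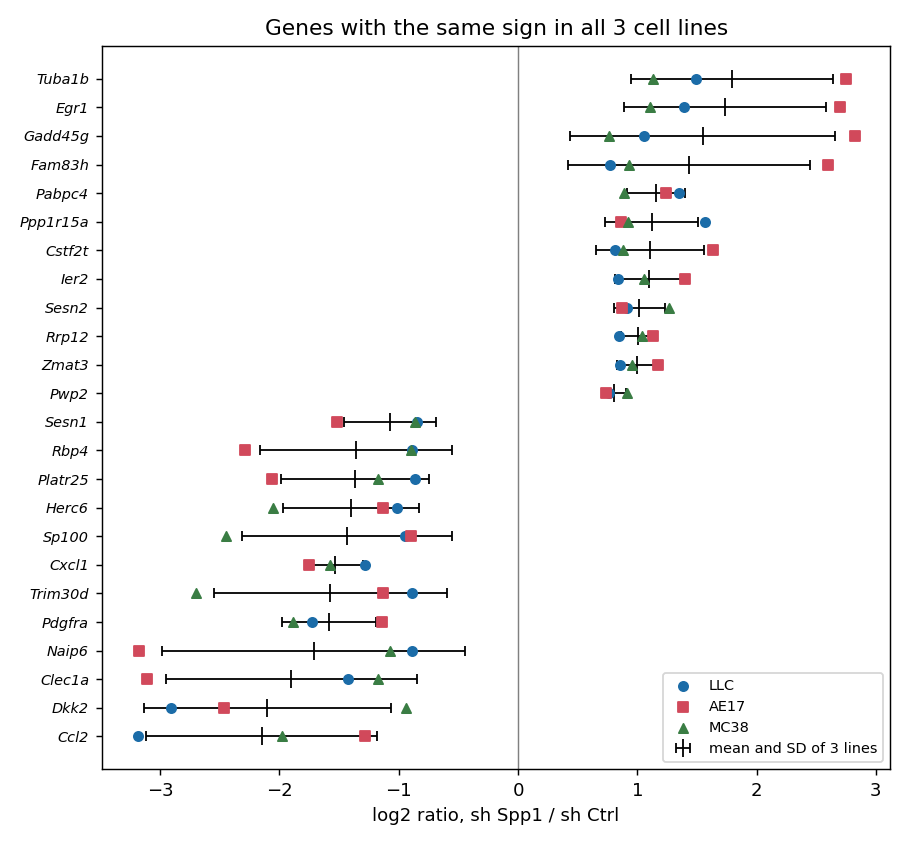
Log2 ratios of sh Spp1 over sh Ctrl (horizontal axis) for the 24 genes ranked by the smallest of their 3 ratios (vertical axis). Coloured symbols are the cell lines, 1 pair of arrays each, and black bars the mean and SD of the 3 lines; Cxcl1 lies between -1.75 and -1.29, and no gene shown passed the adjusted threshold.

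Log2 ratios correlated across genes at Pearson r = 0.142 and Spearman rho = 0.150 between LLC and MC38, 0.0694 and 0.0915 between LLC and AE17, and 0.0444 and 0.136 between AE17 and MC38. In the values as deposited they were higher, at 0.399 and 0.471, 0.163 and 0.245, and 0.172 and 0.296, and centring each array leaves them as they are. Genes are not independent replicates. The sign was the same in all lines for 32.2% of genes, 2816 higher and 2597 lower, where chance gives 25%. That share was 42.8% in the values as deposited and 49.6% with each array centred on its median. These 2 scalings also moved the median log2 ratio of all genes to -0.46 and 0.33 in LLC, -0.23 and 0.22 in AE17, and 0.08 and 0.26 in MC38, from 0.03, -0.04 and 0.02.

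The gene lists fixed beforehand were then compared with all other genes over the 3 lines. Of 33 lists tested, 6 passed camera at an adjusted p under 0.05 with a preset correlation of 0.01. None held with an estimated correlation, where the smallest adjusted p was 0.791. Camera then tests on the 2 residual degrees of freedom of the fit, so hardly any list could pass. For immediate early genes the estimated correlation was -0.029, below the preset value. The loss of a call there does not show that correlation between genes made it. The other called lists had estimates above the preset value: 0.86 for interferon-stimulated genes, 0.44 for extracellular matrix and 0.36 for DNA replication. Targets of p53 had 0.11 and mitosis and G2/M 0.09. For these lists the preset value allowed for less correlation than was estimated, so their camera p-values there can be too small. In fry, which tests a list against no change and not against other genes, the smallest adjusted p was 0.111. Without AE17, whose arrays stood apart from each other, 11 lists passed.

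Immediate early genes, which cells induce within minutes of a stimulus, were higher in each line. The list's median log2 ratio was 0.35 in LLC, 0.49 in AE17 and 0.39 in MC38, and each lay above 99.1% of random lists matched on brightness. Relative to all genes the shifts were 0.32, 0.53 and 0.37, and 0.63, 0.71 and 0.52 in the values as deposited. All 19 members were tested, 9 were higher in every line and 1 lower in every line, and camera gave an adjusted p of 2.21e-05, or adjusted p = 0.791 with an estimated correlation. Ier2 had 0.84, 1.40 and 1.06 in LLC, AE17 and MC38, Fosb 0.74, 0.74 and 1.10, and Zfp36, an RNA-binding regulator of cytokine messages, 1.2, 2.85 and -0.03. Nr4a2 was lower, at -0.54, -0.04 and -0.12. No member reached an adjusted p under 0.05 over all genes, and 0 did when adjusted over the list alone.

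Genes of mitosis and G2/M had medians of -0.40 in LLC, -0.69 in AE17 and -0.12 in MC38, although relative to all genes the values as deposited put the list at 0.10 in LLC, -0.31 in AE17 and 0.15 in MC38. Of 29 tested members, 19 were lower in every line and 2 higher, and camera gave an adjusted p of 1.78e-06, or adjusted p = 0.791 with an estimated correlation. The topoisomerase Top2a had -0.62, -1.61 and -0.37 in LLC, AE17 and MC38, and the checkpoint kinase Ttk -1.15, -1.25 and -0.22. Cdc20 and Ube2c, which act in mitotic exit, were higher, with means of 0.43 ± 0.28 and 0.28 ± 0.12 (SD, n = 3 lines). Over its alternatives the list's adjusted p ran from 1.31e-06 to 0.862. None of the members passed when adjusted over the list alone.

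Genes of DNA replication were lower in LLC, with a median of -0.65 and 27 of 30 members below 0, and lay at 0.05 in AE17 and 0.07 in MC38. Camera gave an adjusted p of 0.0177 over the lines, or adjusted p = 0.791 with an estimated correlation, and 0.924 without LLC, the highest over its alternatives, the lowest being 4.76e-05. In LLC the helicase subunits Mcm4 and Mcm7 had -1.36 and -1.38 and the replication factor Gins2 -1.58, while Cdt1, a licensing factor, had 0.35. Over the lines, Pola1, of the polymerase that primes replication, had -0.84 ± 0.63 and Cdt1 0.52 ± 0.20 (SD, n = 3 lines). None of the members passed when adjusted over the list alone, and in the values as deposited the sign of the list over the lines turned, with a shift relative to all genes of -0.21 in LLC against -0.67.

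Targets of p53, the tumour suppressor that responds to DNA damage, were higher in LLC, where 23 of 26 members were above 0 and the median was 0.69. The shift in LLC relative to all genes was 0.67, and 1.12 in the values as deposited. The medians were 0.07 in AE17 and 0.14 in MC38, and camera gave an adjusted p of 0.00525 over the lines, or adjusted p = 0.791 with an estimated correlation. Without LLC the adjusted p was 0.405, the highest over its camera alternatives at the preset correlation, the lowest being 1.89e-05. The growth arrest gene Btg2 had 1.68, 2.62 and 0.35 in LLC, AE17 and MC38, and Plk2 1.32, 3.37 and -0.99. The cell-cycle inhibitor Cdkn1a had 0.74, 1.2 and 0.51. Sesn1 was lower in every line, as given above, and the death receptor Fas had 0.04, -1.30 and -1.59, the last against a level under the brightness floor. Over all genes 0 members passed, against 3 when adjusted over the list alone.

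Interferon-stimulated genes had opposite directions in the lines. In MC38 all 34 members were lower on the sh Spp1 array, 32 of them by at least 1 log2 unit, and the median was -2.21, a 4.64-fold difference. In AE17 28 were higher, with a median of 1.27, or 2.41-fold, and in LLC 27 were lower, with a median of -0.33. Camera gave an adjusted p of 0.00525 for a fall over the lines, or adjusted p = 0.791 with an estimated correlation. Oas2, an antiviral RNA sensor, went from 10.61 to 6.12 in MC38 and from 7.80 to 8.66 in AE17. Cmpk2 had -2.69 in MC38 and 3.84 in AE17, and Mx1 -0.75 and 2.05, each of the Mx1 ratios with 1 array under the brightness floor. Trim30a was lower in AE17 and MC38, at -0.96 and -2.85, and lay under the floor on both LLC arrays. None of the members passed when adjusted over the list alone. Without MC38 the list was higher in camera, with an adjusted p of 0.0397. At the preset correlation the adjusted p of its alternatives ran from 8.72e-21 to 0.0737. The list for MHC class I antigen presentation had medians of -0.75 in MC38, 0.77 in AE17 and 0.19 in LLC. Its adjusted p over the lines was 0.974.

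**Figure D3:**
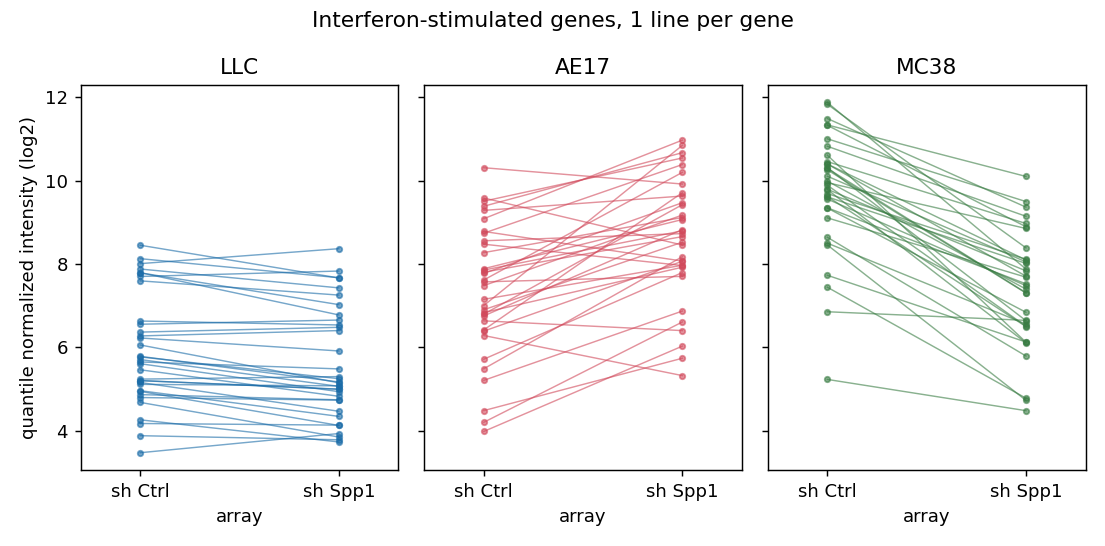
Quantile normalized intensity (log2, vertical axis) of the 34 tested interferon-stimulated genes on the sh Ctrl and sh Spp1 arrays (horizontal axis) of each cell line, 1 line per gene. All 34 were lower on the sh Spp1 array in MC38, 28 were higher in AE17 and 27 were lower in LLC.

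Extracellular matrix genes were higher in AE17, where 30 of 34 members were above 0, 22 of them by at least 1 log2 unit, and the median was 2.0. Their medians were -0.01 in LLC and -0.03 in MC38. Camera gave an adjusted p of 0.00664 over the lines, or adjusted p = 0.791 with an estimated correlation. At the preset correlation it gave 0.272 without AE17, the highest over the alternatives, the lowest being 1.16e-06. The glycoproteins Fn1 and Tnc had 5.51 and 5.92 in AE17, against 0.23 and -0.16 in LLC and 0.45 and 0.06 in MC38. The proteoglycan Dcn and the collagen-binding Sparc had -1.2 and -0.90 in LLC. None of the members passed when adjusted over the list alone.

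Chemokines and cytokines did not pass over the lines, with an adjusted p of 0.156. Their medians were -0.27 in LLC and -0.51 in MC38, below 99.9% of random lists of the same brightness, and -0.12 in AE17. The LLC shift relative to all genes was -0.29, and -0.58 in the values as deposited. Of 24 tested members, 7 were lower in every line and 3 higher in every line. Ccl7, a further monocyte chemoattractant, had -3.63, -0.54 and -2.76 in LLC, AE17 and MC38, and the growth factors Tgfb1 and Tgfb2 had 2.76 and 2.70 in AE17. Adjusted over the list alone, 2 members passed, against 0 over all genes.

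**Figure D4:**
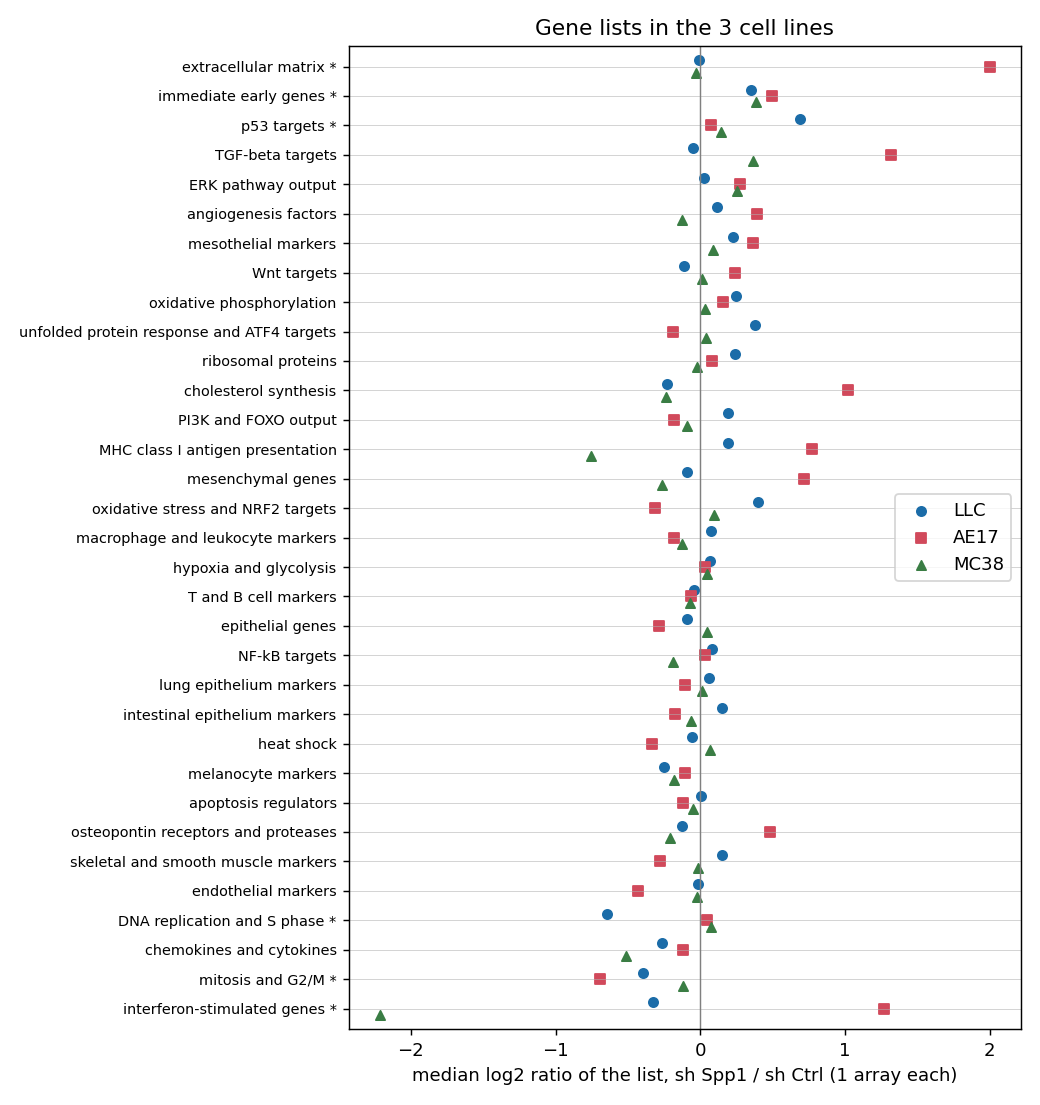
Median log2 ratio of sh Spp1 over sh Ctrl (horizontal axis) of the 33 tested gene lists (vertical axis), ordered by the mean over members and lines. Coloured symbols are the cell lines, 1 pair of arrays each, and asterisks mark the 6 lists with an adjusted p under 0.05 in camera with the preset correlation; interferon-stimulated genes lie at -2.21 in MC38 and 1.27 in AE17.

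The remaining pathway lists had adjusted p between 0.117 and 0.978 over the lines. The medians in LLC, AE17 and MC38 were -0.23, 1.02 and -0.23 for cholesterol synthesis and -0.05, 1.32 and 0.36 for TGF-beta targets, and the AE17 arrays correlated less closely with each other than those of the other lines. Mesenchymal genes had -0.09, 0.72 and -0.26, osteopontin receptors and proteases -0.13, 0.48 and -0.21, and angiogenesis factors 0.12, 0.39 and -0.13. LLC had the higher medians for the unfolded protein response and ATF4 targets, at 0.38, -0.19 and 0.04, and for oxidative stress and NRF2 targets, at 0.40, -0.31 and 0.10. Ribosomal proteins had 0.24, 0.08 and -0.02, and oxidative phosphorylation 0.24, 0.15 and 0.03. The sizes of these LLC shifts depended on the scaling: relative to all genes they were 0.35, 0.37, 0.22 and 0.22 for the 4 lists, and 0.99, 0.92, 0.80 and 0.69 in the values as deposited. ERK pathway output had 0.02, 0.27 and 0.26, NF-kB targets 0.08, 0.03 and -0.19, PI3K and FOXO output 0.19, -0.18 and -0.09, and apoptosis regulators 0.01, -0.12 and -0.05. Wnt targets had -0.11, 0.24 and 0.01, hypoxia and glycolysis 0.07, 0.04 and 0.05, heat shock -0.06, -0.33 and 0.07, and epithelial genes -0.09, -0.29 and 0.04. Adjusted over the list alone, 1 mesenchymal gene passed and 0 genes of the other lists here did.

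Markers of other cell types did not pass over the lines. Their medians in LLC, AE17 and MC38 were 0.08, -0.18 and -0.13 for macrophages and leukocytes, -0.04, -0.06 and -0.07 for T and B cells, and -0.01, -0.43 and -0.02 for endothelium. Intestinal epithelium markers had 0.15, -0.17 and -0.07, lung epithelium 0.06, -0.11 and 0.01, melanocytes -0.25, -0.10 and -0.18, muscle 0.15, -0.28 and -0.01, and mesothelium 0.22, 0.37 and 0.09. Within these lists, in AE17, the mesothelial markers Gata6 and Pdpn had 2.76 and 2.76 and Bnc1 and Cav1 -1.21 and -0.84, and the intestinal keratin Krt20 had -3.04, against a level under the brightness floor.

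The second comparison took each line by itself, by size alone. In LLC 607 of 17054 genes differed by at least 1 log2 unit, 299 higher and 308 lower. In AE17 3291 of 17678 genes did, 1751 higher and 1540 lower, and in MC38 440 of 17014, 150 higher and 290 lower. The SD of the log2 ratios across genes was 0.46 in LLC, 0.94 in AE17 and 0.43 in MC38. The split between higher and lower depended on the scaling. As deposited it was 134 higher and 3216 lower in LLC, 1683 and 2168 in AE17, and 380 and 304 in MC38. With each array centred on its median it was 2707 and 156, 3362 and 854, and 857 and 206.

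In LLC the lowest ratios belonged to the lipid-binding protein Fabp4 at -4.58, Ranbp3l at -4.58, the chemokine Cxcl5 at -4.07, the matrix metalloproteinase Mmp3 at -3.85, the secreted hormone Stc1 at -3.82 and Ccl7 at -3.63. The highest were Cdsn at 2.81, the interleukin-13 receptor subunit Il13ra1 at 2.76, the carbonic anhydrase Car6 at 2.75, Avil at 2.65, the calcium channel subunit Cacna1i at 2.55 and Ano3 at 2.43. Ranbp3l and Fabp4 were also lower in AE17, at -4.24 and -2.67. Mmp3 and Car6 went the other way there, at 2.45 and -3.48, each with an AE17 array under the brightness floor. Fabp4 on the LLC sh Spp1 array, at 3.62, and Ranbp3l on the AE17 sh Spp1 array, at 3.96, lay under the brightness floor, and Ano3 on the LLC sh Ctrl array lay at it, so the sizes of these ratios are approximate.

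In AE17 the highest ratios were those of Tnc and Fn1, given above, the histone gene H2bc12 at 5.50, the cytokine signalling inhibitor Socs2 at 5.50, Tspan6 at 5.11 and the collagen gene Col1a1 at 5.09. The second Socs2 probe set had 1.10. The lowest were the potassium channel Kcnma1 at -7.50, Crip1 at -6.67, Nxf3 at -6.52, the platelet chemokine Ppbp at -6.42, Zfp985 at -5.78 and the gelatinase Mmp2 at -5.67. The second Kcnma1 probe set had a mean level of 4.13, under the brightness floor, against 11.89 for the probe set used, and a ratio of -0.15 in AE17. It did not show the fall, so the Kcnma1 ratio rests on 1 probe set and is in doubt. The probe set used was at a log2 intensity of 12.88 or above on the other 5 arrays and at 5.71 on the AE17 sh Spp1 array. Nxf3 and Zfp985 on that array, at 3.17 and 1.95, and Socs2 on the AE17 sh Ctrl array, at 4.22, lay under the brightness floor of 4.49, where background sets the level, so the sizes and ranks of their ratios are approximate.

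In MC38 the lowest ratios belonged to interferon-inducible genes, namely Phf11d at -4.79, Ifi205 at -4.64, Oas2 at -4.49, Iigp1 at -4.32, Usp18 at -4.0 and Gbp3 at -3.73. All of these were higher in AE17, by between 0.85 and 3.64 log2 units, Gbp3 from a level under the brightness floor. The highest in MC38 were Bpifb4 at 2.44, Ly6g at 2.33, the linker histone H1f10 at 2.29, Ly6f at 2.05, Cep126 at 1.97 and Mcpt8 at 1.93. Phf11d on the MC38 sh Spp1 array, at 4.37, and Ly6f on the sh Ctrl array, at 4.29, lay under the brightness floor.

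The third comparison set the lines against each other with the shRNA as a term. In limma 0 genes passed an adjusted p under 0.05 for AE17 against LLC, 0 for MC38 against LLC and 0 for MC38 against AE17, where the smallest adjusted p was 0.132, 0.055 and 0.0648. At an unadjusted p under 0.05 there were 2171, 1954 and 2232 genes. Without AE17, whose pair set much of the spread, 1040 genes passed for MC38 against LLC, 576 higher in MC38 and 464 lower. Without the AE17 sh Spp1 array alone 514, 1034 and 1093 genes passed for the 3 contrasts, and without the AE17 sh Ctrl array alone 1453, 1027 and 1162. Both of these alternatives were chosen after the data were seen, and the lone AE17 array is assumed to vary like the other lines.

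The genes named here come from the fit without AE17 and were chosen after its values were seen. Higher in MC38 than in LLC were Mmp2 by 5.81 log2 units, the small proteoglycan Bgn by 5.59, Neto2 by 5.62, Dock8 by 5.62, the antiviral Oas1g by 5.55, Itgbl1 by 5.48, Sema3d by 5.34 and Aspa by 5.33. Higher in LLC were the X-inactivation transcript Xist, with a log2 difference of -7.34 ± 0.22 (SE), Nxf3 at -6.72, Sema3e at -5.41, the cyclin Ccnd2 at -5.37, Dpt at -5.36, Grb10 at -5.23, Zdhhc2 at -5.15 and Slc6a15 at -5.11. Their adjusted p in limma lay between 0.000813 and 0.0225, with 2 arrays per line that differ in shRNA and are not replicate cultures. The error in this fit is how the shRNA ratio differs between LLC and MC38, not a spread between cultures of a line. The lower line's mean lay under the brightness floor for Oas1g, Itgbl1, Sema3d, Nxf3, Sema3e, Dpt, Grb10, Zdhhc2 and Slc6a15, so the sizes of these differences are approximate. Many of these genes also differed within AE17, Mmp2 and Nxf3 by the ratios given above. Neto2 went from 4.96 to 7.74 there, Xist from 7.70 to 10.27 and Zdhhc2 from 10.0 to 7.97. Itgbl1, Sema3d and Slc6a15 rose there from under the brightness floor. Dock8, at 5.82 and 5.93, and Ccnd2, at 10.57 and 11.22, differed less. Within MC38, Oas1g went from 10.38 to 7.07.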

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

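The tests in this part, apart from the count of gene lists over other splits of the arrays, were chosen after the result was seen, as was the rule for the lists named next. Each line has 1 pair of arrays, so the differences between lines listed here were not tested. They are lists whose median lay outside the central 95% of random lists in opposite directions in different lines.

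Interferon-stimulated genes had a median log2 ratio of 1.27 in AE17, -0.33 in LLC and -2.21 in MC38. MHC class I antigen presentation had 0.77 in AE17 and -0.75 in MC38. Mesenchymal genes had 0.72 in AE17 and -0.26 in MC38. Cholesterol synthesis had 1.02 in AE17, -0.23 in LLC and -0.23 in MC38. Osteopontin receptors and proteases had 0.48 in AE17 and -0.21 in MC38.

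The AE17 arrays were far apart. Scaling of the arrays is argued against, since the SD of the AE17 ratios exceeded that of both other lines by at least 1.62 times quantile normalized, as deposited and centred. A swap with another array of the series is argued against because each LLC and MC38 array correlated best with its partner, by at least 0.0138. Cell populations that differ in their chromosomes were not decided: the SD of the medians of 50 neighbouring genes beyond that of shuffled genes, as a share of the SD of the pair's log2 ratios, was 0.195 in AE17, 0.1 in LLC and 0.179 in MC38, and 0.117 to 0.214 between different lines, a range that holds MC38 as well. A wrong label or another cell population stays open, and so does a response of AE17 cells to the shRNA, with 18.6% of genes differing by at least 1 log2 unit, since 1 array per shRNA cannot separate them.

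Interferon-stimulated genes lay on opposite sides of 0 in MC38 and AE17. Scaling of the arrays is argued against, since the list's shift relative to all genes was at least 1.31 in size, on its own side of 0, in both lines, quantile normalized and as deposited, and centring leaves the deposited value as it is. The share of members on the list's side of 0, at least 82.4% in MC38 and in AE17, was no test of a few members carrying the median. A median of that size already fixes much of that share. Interferon signalling in the cultures at harvest may account for it: the MHC class I list, which interferon also induces and which shares 0 genes with the first, had a median of -0.75 in MC38 and 0.77 in AE17. In LLC the lists did not move together, with medians of -0.33 for interferon-stimulated genes and 0.19 for MHC class I. The latter lay above 84.5% of random lists of the same brightness. The account of interferon signalling therefore rests on MC38 and AE17. What set such signalling, including a response to the hairpin or to its vector, was not tested, and for AE17 the doubt about the array applies.

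The shRNA comparison gave 0 genes, so all 10 splits of the 6 arrays into 3 and 3 gave as many by construction, which decides nothing. The highest of the others gave 1301, in the splits that part the AE17 arrays alone, a structure of the samples that restates how far apart that pair is. The other splits that part 3 pairs, as the real one does, gave 0. The real split gave 6 lists past the threshold, 9 of the 10 splits gave as many, and the highest of the others gave 11. With 10 splits the share cannot be under 0.05. Among the splits that part all 3 pairs, the real one had 1042 genes at an unadjusted p under 0.05 and the others 367, 465 and 416. With 3 pairs that share cannot go below 0.25, so the higher count does not separate the hairpin from chance. As deposited, the sh Spp1 array of each line also had the lower median and the wider spread. A technical difference between arrays that goes with the label was therefore not separated from the hairpin. That limit holds for this count, for the genes with the same sign in all lines and for the lists.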

How the results depend on the processing

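The count of 0 genes for the shRNA was the same in 14 of 15 alternatives, leaving out each line and dropping the replicate block included. An unadjusted p under 0.01 gave 102. The smallest adjusted p ranged from 0.122 with each array centred to 0.932 without the block. The Spp1 alternatives were not run, since its level was not analysed here. Precision is limited by 3 pairs of arrays and, for dim genes, by signal near background.

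Counts between lines, 0 in the reported fit, moved as follows. As deposited, 102, 220 and 286 genes passed for AE17 against LLC, MC38 against LLC and MC38 against AE17. With an intensity trend and a robust prior together 1, 55 and 37 passed, and with no shRNA term 9, 84 and 93. Without the AE17 sh Spp1 array 514, 1034 and 1093 passed, and without the AE17 sh Ctrl array 1453, 1027 and 1162, both chosen after seeing the data. For MC38 against LLC, no brightness filter gave 44, the 50th percentile 42 and array weights 436. Leaving out AE17 gave 1040. MC38 against AE17 gave 27 at the 50th percentile. The cause was not tested, beyond the AE17 pair carrying much of the spread, which leaving out either of its arrays removes.

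Genes differing by at least 1 log2 unit numbered 3350 in LLC and 684 in MC38 as deposited, and 2863 and 1063 with arrays centred. At 1.5 log2 units they numbered 145 in LLC, 1543 in AE17 and 146 in MC38, by construction. The share of genes with 1 sign in all lines was 49.6% with arrays centred. Lists past the threshold numbered 20 as deposited, 19 with arrays centred, 0 with an estimated correlation, 0 with fry, and 4 to 11 with a line left out, 11 without AE17.

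Directions turned as follows, with shifts relative to all genes. With a line left out, interferon-stimulated genes ran from -1.36 without AE17 to 0.514 without MC38, extracellular matrix from -0.0685 without AE17 to 0.821 without LLC, and DNA replication from -0.381 without MC38 to 0.0349 without LLC. DNA replication had 0.0823 as deposited and 0.0823 with arrays centred. Mitosis and G2/M turned in camera with arrays centred, where its median was -0.052, and within LLC and MC38 it was 0.0966 and 0.148 as deposited, which centring leaves as it is, although below at least 99% of random lists of the same brightness. The cause was not tested.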

Other observations

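The tests in this part were chosen after the result was seen.

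Hox genes, which mark position along the body axis, were counted without an enrichment test. Of 36 at or above the floor on some array, 15 differed by at least 1 log2 unit between the AE17 arrays, where 18.6% of all genes did, 0 between the LLC arrays and 2 between the MC38 arrays. Hoxc10 went from 5.31 to 8.55 in AE17. The simple-epithelium keratin Krt8 went from 11.08 to 6.47 in AE17, while it lay at 8.88 and 8.31 in LLC and at 6.69 and 7.14 in MC38. Its partner keratin Krt18 lay at 5.01 and 4.67 in AE17, and of the epithelial list 10 members were higher and 11 lower there. Xist was at 7.70 on the AE17 sh Ctrl array and 10.27 on the sh Spp1 array, at 11.98 and 11.83 in LLC and at 4.89 and 4.24 in MC38. Msln, a mesothelial marker, was at 9.87 and 9.96 in MC38 and at 5.13 and 5.34 in AE17. These genes were chosen after their values were seen.

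Genes on chromosome 5, which carries Spp1 in assembly GRCm38.p6, were lower on the MC38 sh Spp1 array. Their median log2 ratio over 1023 genes was -0.17 relative to all genes, with 68.6% below the median of all genes and an adjusted p of 5e-04 in a permutation of gene positions over 60 tests. The permutation p of 1e-04 is the smallest it can give, and genes are not independent replicates. In MC38 chromosomes 18, 8 and 17 also passed, with medians of 0.09, 0.05 and 0.04. In LLC 4 chromosomes passed, and in AE17, with an SD of the log2 ratios of 0.94 against 0.43 in MC38, 12 did, where the medians of chromosomes 15, 16 and 1 were 0.19, 0.18 and -0.17. A lower chromosome 5 copy number in the MC38 sh Spp1 cells was not decided. The median lay below that of all genes in 90% of windows of 50 neighbouring genes. Shuffled genes of the chromosome gave 95% to 100%, so a high share of windows follows from the share of genes below. The 90% lay under the lowest of 200 shuffles, so neighbouring genes were less uniformly low than shuffled ones. Scaling of the arrays is argued against, since the median was -0.17 quantile normalized and as deposited. Whether such a loss would lower Spp1 apart from the hairpin was not tested.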
